A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

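The deposited table gives whole-number counts of reads per gene for 24 libraries of Saccharomyces cerevisiae. Per the labels, the RNA was polyA RNA from log-phase cells treated with cycloheximide, polysome-bound RNA was fractionated on sucrose gradients, and libraries followed standard Illumina protocols. Per the series design, biological duplicates were made of each strain and RNA pool, and reads of the same barcode from 2 sequencing lanes were merged. The submitters' processing notes name cutadapt 1.4, SAMtools 0.1.19, RSEM 1.2.18 and the build sacCer3, with no role or order. Which of these tools made the counts, and how reads matching more than 1 gene were counted, is not given in the sources used here. Counts of paralogs and overlapping genes are uncertain for that reason.

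The table holds 6369 genes, of which 5908 matched the R64 reference table by systematic name. Coordinates and lengths come from that table. Each column was assigned to its sample by its label, and 0 columns were left unassigned. Each pair of duplicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.85 to 34.6, so that every library counts as 1 replicate. P-values rest on a spread pooled over the duplicates of all 12 groups, not on that of the compared groups alone. The chi-square per degree of freedom was 2 in wild-type input and 1.85 in ΔRPL22B input. It was 20.1 and 34.6 in light polysomes of ΔRPL22A and ΔRPL22B.

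Tests used edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 5380, and libraries were scaled by TMM. One model with a mean for each of the 12 groups was fitted to all 24 libraries, with 12 residual degrees of freedom and a prior of 16.1, and contrasts were tested by the quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. Shifts between pools were tested as interactions, the difference between strains in the log ratio of a pool to input. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled. With no change, a share of about 0.05 of the tested genes would have an unadjusted p under 0.05, so counts at that threshold are not calls. Total counts were 2435632 to 10947937 per library and 314212 to 1950344 outside the ribosomal DNA, and 5456 to 6055 genes were detected.

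Before the data were examined, 34 gene lists were fixed, of which 33 had tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 33 lists of a comparison, and again with an estimated correlation. In total 114 list tests passed with the preset correlation over 13 comparisons, and the sign of 0 of their medians turned under the other scalings. Named genes followed a rule fixed beforehand. They are the targeted genes, and the up to 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM and groups that do not overlap. Of each list with a passing test or at least 3 called members, up to 4 members with the smallest adjusted p were eligible. Folds against a group at 0 use a floor of 3 counts over the group, and ratios to 1 to 3 counts have an exact 95% counting interval.

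The test was tried on simulated counts with 200 changed genes, drawn from those with a mean count of at least 20. The rates do not cover genes counted lower. For input of ΔRPL22A against wild type (5246 genes) it recovered 28% of genes changed 2-fold and 97% of those changed 4-fold with 6 false calls. For the heavy polysome to input ratio in the same strains (5283 genes) it recovered 4% and 58% with 3 false calls, so that 2-fold shifts between pools were mostly not detectable.

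Alternatives fixed beforehand were relative log expression scaling, TMM without ribosomal protein and mitochondrial genes, no low-count filter and DESeq2 1.42.0. Also fixed beforehand were fits of only the compared groups, a block for the replicate number, and leaving out each library in turn. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other groups. Removal of the ribosomal DNA rows was not fixed beforehand. Leaving out the 4 libraries closest to another pool was added after the data were seen. These were wild-type heavy polysome replicate 2, ΔRPL22A input replicate 1, ΔRPL22A light polysome replicate 2 and ΔRPL22B light polysome replicate 1. All other scalings moved the median log2 fold change by less than 0.1. With 2 libraries per group, splits of the samples and tests for single outlying libraries were not run.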

Results

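Budding yeast carries 2 genes, RPL22A and RPL22B, for the large-subunit ribosomal protein Rpl22. The libraries came from log-phase cells (OD 0.6 to 0.8) of a wild-type strain and of strains lacking RPL22A (ΔRPL22A) or RPL22B (ΔRPL22B). Cells were treated with cycloheximide, which holds ribosomes on mRNA, and extracts were separated on sucrose gradients. RNA was sequenced from 4 pools per strain: input RNA, the monosome fraction, and the low and high polysome fractions, called light and heavy polysomes here. Each of the 12 strain and pool groups holds 2 libraries, biological duplicates per the series design, so that the 24 libraries ask which mRNAs change in level, and which in their distribution over ribosome fractions, when 1 paralog is missing. The series title places the work in the setting of oxidative stress, and the labels name no stress treatment.

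Total counts per library ranged from 2435632 to 10947937. Between 62.5% and 97.1% of them fell on 7 rows at the ribosomal DNA locus, although the labels give the molecule as polyA RNA, which left 314212 to 1950344 counts per library for all other genes. The monosome libraries reached the highest shares, 83.4% to 97.1%, but the ranges of the pools overlapped. The share was 68.2% to 88.3% in input, 62.5% to 88.6% in light polysomes and 75.9% to 92.7% in heavy polysomes. The split within the locus also followed the pools: YLR154W-E took 63.9% to 96.9% of the ribosomal DNA counts in monosomes and 47.0% to 82.9% in heavy polysomes, but 6.02% to 9.53% in input and 5.96% to 20.4% in light polysomes. Values below are log2 fold changes ± standard error from edgeR, with n = 2 libraries per group, or means ± SD in TMM-scaled CPM.

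The targeted genes were examined first. RPL22B (YFL034C-A, chromosome VI, 64243 to 64932) had 0 counts in all 8 ΔRPL22B libraries, 1329 in the 8 wild-type libraries and 6354 in the 8 ΔRPL22A libraries. RPL22A (YLR061W, chromosome XII, 263194 to 263948) was barely counted anywhere, with 25 counts in wild type, 3 in ΔRPL22A and 40 in ΔRPL22B, so its row checks the ΔRPL22A label only weakly. In ΔRPL22A the remaining paralog RPL22B rose in every pool. It stood at 63.2 ± 14.6 CPM in input against 19.4 ± 2.13 CPM in wild type, 3.24-fold higher (log2 1.70 ± 0.30, adjusted p = 0.000865). The rise was 1.66 ± 0.30 in monosomes (adjusted p = 0.0011), 2.04 ± 0.30 in light polysomes (adjusted p = 9.96e-05) and 1.96 ± 0.31 in heavy polysomes (adjusted p = 0.000268). How reads shared by the paralogs were assigned is not given in the sources used here.

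**Figure D1:**
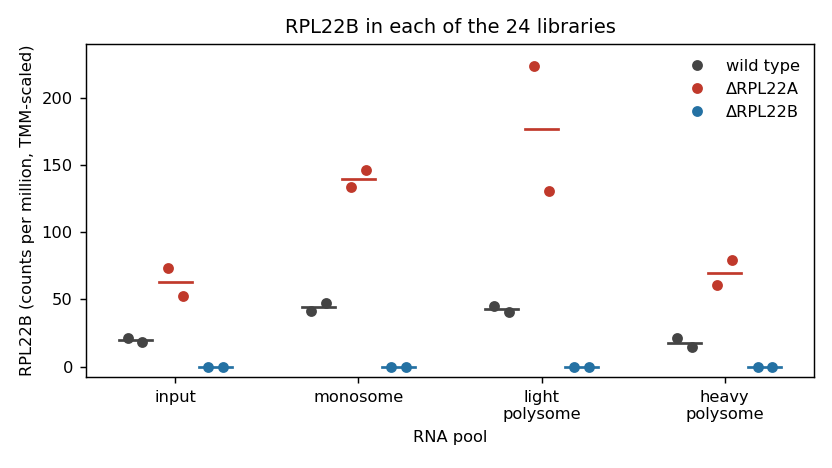
RPL22B level in TMM-scaled CPM (y axis) in the 4 RNA pools (x axis), with each library as a point and the mean of 2 libraries as a bar. The ΔRPL22A libraries lie above those of wild type in every pool, and the ΔRPL22B libraries are all at 0.

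The wild-type and the deletion libraries differed in mating-type and nutritional marker genes. All 4 genes of the α-specific list were higher in both deletion strains, and the a-specific genes were higher in wild type. In input, MF(ALPHA)1, the α-factor gene, had 5819 counts in ΔRPL22A, 3160 in ΔRPL22B and 0 in wild type, at least 1470-fold and 738-fold higher against a floor of 3 counts over the group. MFA2, an a-factor gene, had 428 counts in wild-type input, 3 in ΔRPL22A (ratio 188, 95% counting interval 63.9 to 915) and 2 in ΔRPL22B (ratio 305, 84.0 to 2530). The HMRA1 row, annotated at a silent mating-type cassette, had 374 counts in the wild-type libraries and 0 in the 16 deletion libraries. The counts do not show from which locus these reads came. MET17 had 0 counts in the 8 wild-type libraries and 824 and 788 in the ΔRPL22A and ΔRPL22B libraries, and LYS2 had 955, 2 and 0. Every comparison with wild type below therefore carries this difference. ΔRPL22A and ΔRPL22B express the same mating-type set, MET17 and no LYS2 above 2 counts, but they differ at HIS3, with 2447 and 784 counts, and 6 of the genes called between their inputs are targeted genes or on the mating-type and marker lists. Intervals and floors cover counting error only.

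**Figure D2:**
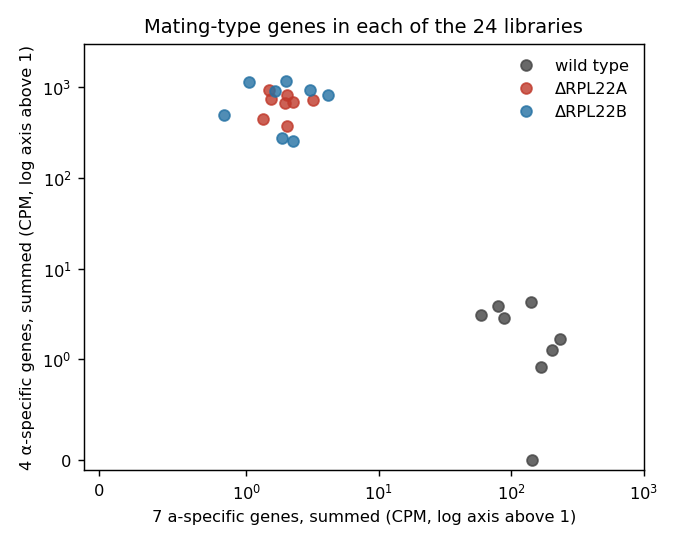
Summed CPM of 7 a-specific genes (x axis) and 4 α-specific genes (y axis), both on a scale that is logarithmic above 1, with 1 point per library. The 8 wild-type libraries lie at the lower right and the 16 deletion libraries at the upper left.

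In input RNA of ΔRPL22A against wild type, ARG4 (argininosuccinate lyase) rose from 5.90 ± 1.47 to 28.6 ± 2.04 CPM (log2 2.29 ± 0.29, adjusted p = 4.63e-06), ARG7 by 2.41 ± 0.32 and HIS5 by 1.77 ± 0.26. The glucokinase gene GLK1 fell by 2.33 ± 0.34 and the enolase gene ENO1 fell by 2.13 ± 0.37. The urea amidolyase gene DUR12 (YBR208C) fell by 3.16 ± 0.33 and the cell wall mannoprotein gene TIR1 fell by 2.54 ± 0.31. Beyond the listed marker genes, the largest changes also included rises of SHB17 (sedoheptulose bisphosphatase, 3.27 ± 0.34), AFB1 (an α-cell protein that binds a-factor, 5.41 ± 0.42) and GCV3 (glycine cleavage, 1.94 ± 0.38) and falls of SAM2 (S-adenosylmethionine synthetase, -1.91 ± 0.27) and TDH1 (glyceraldehyde phosphate dehydrogenase, -2.69 ± 0.50). In all, 250 of 5380 genes passed at an adjusted p under 0.05, 116 higher and 134 lower, and 227 of them are not targeted genes or on the fixed mating-type and marker lists, which lack AFB1 and HMRA1.

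Of 46 tested genes in the list of amino acid biosynthesis genes under Gcn4, the activator of the amino acid starvation response, 17 rose, 1 fell and 28 did not pass, and adjusted over the list alone 24 rose and 3 fell. The list stood 0.73 above other genes (camera adjusted p = 6.14e-13, and adjusted p = 0.0509 with an estimated correlation). Of 35 general stress genes under Msn2 and Msn4, 10 fell and 25 did not pass (adjusted over the list alone 12 fell and 1 rose), with HSP78, a mitochondrial disaggregase, falling by 3.76 ± 0.58 (camera adjusted p = 1.53e-06, and adjusted p = 0.00167 with an estimated correlation). Of 18 phosphate regulon genes 4 fell (adjusted over the list alone 7), among them the acid phosphatase gene PHO12, which fell by 2.26 ± 0.33 (camera adjusted p = 5.18e-05, and adjusted p = 0.0252 with an estimated correlation). Of 15 haploid and pheromone response genes 7 rose and 1 fell (adjusted over the list alone 10 and 1), including AGA1 (2.65 ± 0.32), KAR4 (1.90 ± 0.29) and FIG2 (2.02 ± 0.32), with a camera adjusted p of 1.84e-05 and an adjusted p = 0.0027 with an estimated correlation. All 7 a-specific genes fell and all 4 α-specific genes rose (adjusted p = 1.31e-05 for each with an estimated correlation).

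The other lists that passed camera's preset test in this comparison lost their call with an estimated correlation. Of 22 glycolysis and fermentation genes 4 fell (adjusted over the list alone 5, camera adjusted p = 6.19e-05, and adjusted p = 0.332 with an estimated correlation), and of 21 chaperone genes 3 fell (8, 6.69e-05, and adjusted p = 0.138 with an estimated correlation). Of 107 ribosome biogenesis genes 8 rose (adjusted over the list alone 13, camera adjusted p = 3.4e-06, and adjusted p = 0.334 with an estimated correlation). Of 6 mitochondrially encoded genes 3 rose, COX1 by 2.12 ± 0.38 (adjusted over the list alone 5, camera adjusted p = 0.000235, and adjusted p = 0.18 with an estimated correlation). On the large-subunit ribosomal protein list of 79 genes 1 rose and 3 fell, the same numbers adjusted over the list alone. RPL22B was up and RPL7B down by -1.87 ± 0.26. The list as a whole stood 0.38 above other genes (camera adjusted p = 0.000365, and adjusted p = 0.662 with an estimated correlation). It also holds RPP1 (YHR062C), a ribonuclease P subunit gene and not a ribosomal protein gene. None of the 57 small-subunit genes passed (0 also adjusted over the list alone, camera adjusted p = 0.00871 upward, and adjusted p = 0.717 with an estimated correlation). The tricarboxylic acid cycle (1 rose and 2 fell of 20, adjusted p = 0.332 with an estimated correlation), iron regulon (3 rose and 1 fell of 30, adjusted p = 0.18) and cell cycle regulator lists (1 rose and 1 fell of 22, adjusted p = 0.18) had camera adjusted p-values of 0.0353, 0.0108 and 0.00631. Adjusted over the list alone the counts were 1 and 4, 6 and 1, and 1 and 2.

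The count of 250 fell to 104 without wild-type input replicate 1, 58 without wild-type input replicate 2 and 59 without ΔRPL22A input replicate 1, and 31 of 67 called named genes passed in each such fit. GCV3 lost its call without wild-type replicate 1 (adjusted p = 0.0589) or ΔRPL22A replicate 1 (0.079), and TDH1 without wild-type replicate 2 (0.112) or ΔRPL22A replicate 1 (0.109). Without ΔRPL22A replicate 1 the large-subunit (0.339), small-subunit (0.69) and iron (0.057) lists lost theirs. The biogenesis list did so without ΔRPL22A replicate 2 (0.104), the iron list without wild-type replicate 1 (0.0509), and the tricarboxylic acid cycle list without either of the last 2 libraries (0.212 and 0.0953). With the ribosomal DNA rows left out of the scaling 308 genes passed, 181 higher and 127 lower, so that the share of higher calls moved from 46.4% to 58.8%; DESeq2 called 213, 127 higher and 86 lower. With only the compared groups fitted 545 passed. ΔRPL22A input replicate 1 was among the 4 libraries closest to another pool. It correlated at 0.96 with its replicate and at 0.947 with ΔRPL22A light polysome replicate 2.

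Input of ΔRPL22A was also compared with that of ΔRPL22B, which expresses the same mating-type genes. HIS5 rose by 1.88 ± 0.26 (adjusted p = 4.29e-05), ARG7 by 1.94 ± 0.29 and ARG4 by 1.75 ± 0.28. GLK1 fell by 2.46 ± 0.33, ENO1 fell by 2.59 ± 0.38, from 184.8 ± 19.6 to 30.7 ± 4.90 CPM, and TDH1 fell by 3.28 ± 0.51. DUR12 fell by 3.04 ± 0.33, TIR1 by -2.57 ± 0.31, the multidrug transporter gene PDR5 by -1.83 ± 0.27 and RPL7B by -1.73 ± 0.26. GCV3 rose by 2.28 ± 0.38, the iron-sulfur scaffold gene ISU2 by 1.92 ± 0.34, the mitochondrial intron maturase gene AI2 by 1.82 ± 0.32 and HIS3, a common auxotrophic marker, by 1.76 ± 0.30. The remaining genes with the largest changes were REE1 (1.92 ± 0.45), RIB5 (1.80 ± 0.41), RPL8A (-1.53 ± 0.36) and TYE7 (-1.50 ± 0.26). Altogether 283 genes passed, 125 higher and 158 lower. Next to RPL22B on chromosome VI, MIL1 was lower by -1.25 ± 0.32, and the flanking MOB2 and HAC1 did not pass (0.54 ± 0.36 and 0.67 ± 0.37).

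Of the 46 amino acid genes 20 rose and 1 fell (adjusted over the list alone 26 and 2), and the list stood 0.84 above other genes (camera adjusted p = 9.81e-18, and adjusted p = 0.0502 with an estimated correlation). GCN4 itself was higher by 0.91 ± 0.27 (adjusted p = 0.0486, and 0.0562 with a block for the replicate number). Of 35 general stress genes 10 fell (adjusted over the list alone 15), with HSP78 down by -4.09 ± 0.55, the disaggregase gene HSP104 by -2.18 ± 0.33 and the nicotinamidase gene PNC1 by -2.25 ± 0.40 (camera adjusted p = 3.73e-09, and adjusted p = 0.000965 with an estimated correlation). It was the 1 list of 33 whose call held with an estimated correlation. Of 22 glycolysis and fermentation genes 5 fell (5 adjusted over the list alone, adjusted p = 0.295 with an estimated correlation), of 20 tricarboxylic acid cycle genes 7 fell (2 rose and 9 fell adjusted over the list alone, 0.179) and of 21 chaperone genes 3 fell (11 adjusted over the list alone, 0.143). Of 107 ribosome biogenesis genes 12 rose (23 adjusted over the list alone, adjusted p = 0.219 with an estimated correlation). The large-subunit list (1 rose and 2 fell of 79, the same adjusted over the list alone) and the small-subunit list (0 of 57 by either adjustment) stood 0.69 and 0.54 above other genes, with adjusted p = 0.389 and 0.522 with an estimated correlation. Mitochondrially encoded (2 of 6 rose, 4 adjusted over the list alone) and iron regulon genes (2 of 30 rose, 5 adjusted over the list alone) were higher as lists, with adjusted p = 0.295 and 0.219 with an estimated correlation. Phosphate regulon (3 of 18 fell, 8 adjusted over the list alone) and cell cycle genes (2 of 22 fell, 2 adjusted over the list alone) were lower, with adjusted p = 0.108 and 0.179 with an estimated correlation. By camera's preset test the adjusted p-values of these 10 lists, from glycolysis to cell cycle, were at most 0.0167. The list of 5 genes at the RPL22 loci passed it too (0.0172, and adjusted p = 0.142 with an estimated correlation), but it holds RPL22B, which is deleted in ΔRPL22B.

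The 283 calls became 40 without ΔRPL22A input replicate 1, 490 without ΔRPL22A replicate 2, 38 without ΔRPL22B replicate 1 and 82 without ΔRPL22B replicate 2, and 20 of 59 called named genes passed in each. GCN4 lost its call in all 4 of these fits (adjusted p = 0.25, 0.0781, 0.311 and 0.195). MIL1 lost its call in 3 of them (0.359, 0.151 and 0.136 in the same order, without ΔRPL22A replicate 2). Without ΔRPL22A replicate 1 so did REE1 (0.246), RIB5 (0.205), RPL8A (0.246), TYE7 (0.0683) and the iron list (0.0611). Without ΔRPL22B replicate 1 so did REE1 (0.208), RIB5 (0.0663), RPL8A (0.102) and the iron list (0.108), and without ΔRPL22B replicate 2 RIB5 (0.155) and RPL8A (0.0632). The higher share of calls moved from 44.2% to 59.0% with relative log expression scaling (354 genes, 209 higher and 145 lower) and to 61.0% with ribosomal DNA rows left out (372, 227 and 145), and DESeq2 called 268, 181 higher and 87 lower. With only the compared groups fitted 713 passed.

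**Figure D3:**
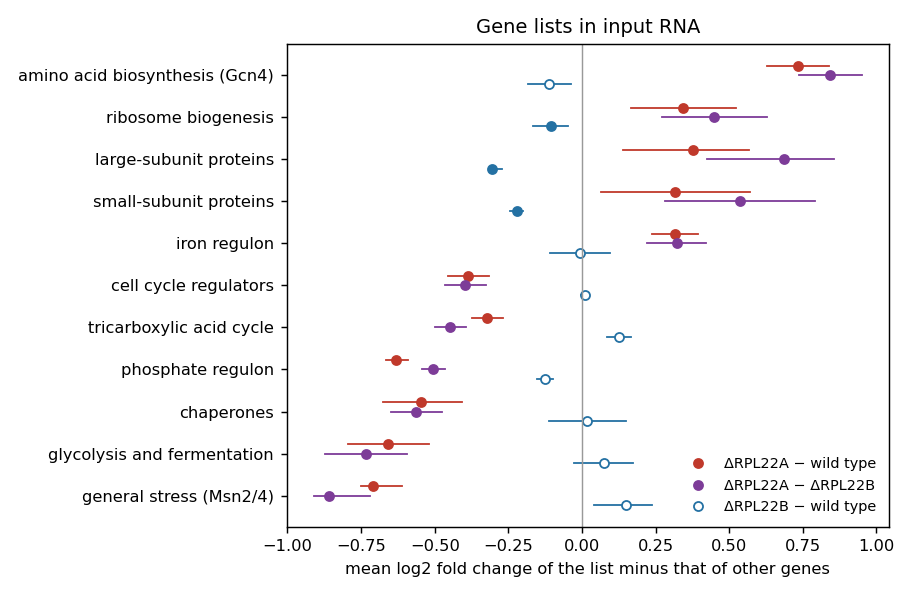
Mean log2 fold change of each gene list minus that of all other genes in input RNA (x axis) for 11 lists and the 3 strain comparisons, with points filled where camera's preset test gave an adjusted p under 0.05 and lines spanning the values with 1 library left out. Amino acid biosynthesis genes stand 0.73 and 0.84 above other genes in the 2 comparisons of ΔRPL22A, and general stress genes stand at -0.71 and -0.86.

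Input of ΔRPL22B differed from wild type at 18 genes, 8 higher and 10 lower, and 14 of these were targeted genes or on the mating-type and marker lists. The other 4 were SHB17, LYS9, AFB1 and HMRA1, the last 2 named after their values were seen. The α-specific genes SAG1 (3.75 ± 0.34) and MF(ALPHA)2 (7.40 ± 0.55) rose, and STE2, the α-factor receptor gene, fell by 6.55 ± 0.48. SHB17 rose by 2.57 ± 0.33, to 29.9 ± 2.43 CPM (adjusted p = 7.5e-06), and it also rose in ΔRPL22A. LYS9 in lysine synthesis fell by 1.17 ± 0.24 (adjusted p = 0.015). RPL22B itself, at 331 counts against 0, was at least 157-fold lower. Of the amino acid list 1 of 46 fell (camera adjusted p = 0.055), and of the general stress list 0 of 35 passed (adjusted p = 0.0839).

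Ribosomal protein genes stood slightly lower as lists in ΔRPL22B input: 1 of 79 large-subunit genes, RPL22B, passed and 0 of 57 small-subunit genes, the same adjusted over the list alone, with mean differences of -0.31 and -0.22 (camera adjusted p = 1.05e-07 and 0.00014, and adjusted p = 0.72 and 0.797 with an estimated correlation). RPS6B was at -0.48 ± 0.40 and RPS17B at -0.56 ± 0.48. Purine and ribosome biogenesis genes, with 0 called of 18 and 107 by edgeR and 0 adjusted over the list alone, had camera adjusted p-values of 0.0138 and 0.0199 (adjusted p = 0.688 and 0.797 with an estimated correlation). Of the haploid and pheromone genes 1 of 15 rose, AGA1 by 1.64 ± 0.32 (adjusted over the list alone 6, adjusted p = 0.000285 with an estimated correlation). The a-specific (6 of 7 fell, 7 adjusted over the list alone) and α-specific genes (4 of 4 rose) held with an estimated correlation (adjusted p = 1.82e-08 and 2e-08). The list of 5 genes at the RPL22 loci passed (camera adjusted p = 9.53e-06, and adjusted p = 0.00292 with an estimated correlation), but it holds the deleted RPL22B. Of the genes flanking the loci, FRS1 (-0.01 ± 0.26), MIL1 (0.40 ± 0.31), MOB2 (-0.35 ± 0.38) and HAC1 (-0.30 ± 0.37) did not pass. LYS9 lost its call without wild-type replicate 2 (adjusted p = 0.701) or either ΔRPL22B library (0.131 and 0.849), and AGA1 without wild-type replicate 1 (0.363) or 2 (0.169) or ΔRPL22B replicate 1 (0.307). The purine and biogenesis lists lost theirs without wild-type replicate 1 (0.389 and 0.707) or ΔRPL22B replicate 1 (0.126 and 0.25). At an unadjusted p under 0.05 79 genes passed, a smaller share of those tested than 0.05. DESeq2 called 17, and 39 passed with only the compared groups fitted. Wild-type and ΔRPL22B input had the lowest duplicate chi-squares per degree of freedom (2 and 1.85), while the test used a spread pooled over all groups. The small number of calls may partly come from this.

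Calls shared by comparisons with a group of libraries in common were counted. Between ΔRPL22A and ΔRPL22B input against wild type, 8 genes were higher and 9 lower in both, and 1 was opposite. Independent lists would give 0.17 and 0.25, and 20 simulations of unchanged groups gave 0. Of the 18 genes called in ΔRPL22B input, 14 were targeted genes or on the mating-type and marker lists. The opposite gene was RPL22B, deleted in ΔRPL22B. The shared calls therefore largely restate the difference in strain background. The fold changes correlated across genes at r = 0.473, against 0.543 simulated, and their covariance was 0.197 against 0.098 simulated. Without the targeted genes and the mating-type and marker lists the covariance over 5347 genes was 0.0613 and r was 0.248, both below the simulated values for all genes. The simulations took each gene's spread from all 12 groups. Wild-type input, the group in common, had a duplicate chi-square per degree of freedom of 2, among the lowest. The simulated values may thus be too high here, and whether changes beyond these lists are shared cannot be told. ΔRPL22A against wild type and against ΔRPL22B shared 72 higher and 88 lower calls (2.70 and 3.94 for independent lists, 0.05 simulated), with a covariance of 0.403 against 0.0825 simulated and r = 0.740 against 0.480. The group in common is wild-type input for the first pair of comparisons and ΔRPL22A input for the second. Its 2 libraries were not split between comparisons, so part of any excess may come from them. Genes are not independent replicates.

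In heavy polysomes, ΔRPL22A differed from wild type at 177 genes, 75 higher and 102 lower. ARG4 rose by 2.09 ± 0.31 (adjusted p = 5.99e-05), SHB17 by 3.76 ± 0.36, AI2 by 2.36 ± 0.42, and the glycine cleavage gene GCV2 by 1.92 ± 0.36. The ribosomal protein gene RPL8A fell by 3.11 ± 0.39, from 233.9 ± 21.7 to 27.6 ± 14.4 CPM, RPL18B fell by 2.05 ± 0.28 and RPL7B fell by 2.13 ± 0.31. GLK1 fell by 2.98 ± 0.34, ENO1 by -2.66 ± 0.38, TDH1 by -3.13 ± 0.53, DUR12 by -2.74 ± 0.34, TIR1 by -3.37 ± 0.36, and LYS9 by -1.91 ± 0.25. The marker genes moved as in input: MF(ALPHA)1 (9.30 ± 0.60), MF(ALPHA)2 (6.28 ± 0.54) and SAG1 (4.63 ± 0.41) were higher, STE2 (-5.36 ± 0.45) and MFA2 (-7.51 ± 0.60) lower, and LYS2 had 1 count against 228 (ratio 448, 95% counting interval 79.6 to 17800).

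Of 35 general stress genes 7 fell (13 adjusted over the list alone), with the glycerol phosphate dehydrogenase gene GPD1 down by -1.99 ± 0.33 (camera adjusted p = 1.89e-07, and adjusted p = 0.000954 with an estimated correlation). Of 46 amino acid genes 9 rose and 2 fell (23 and 6 adjusted over the list alone, camera adjusted p = 2.94e-06, and adjusted p = 0.189 with an estimated correlation). Of 107 ribosome biogenesis genes 8 rose (39 adjusted over the list alone, camera adjusted p = 3.64e-16, and adjusted p = 0.0702 with an estimated correlation). Of 22 glycolysis genes 5 fell (12 adjusted over the list alone, camera adjusted p = 1.41e-13, and adjusted p = 0.0619 with an estimated correlation), and of 21 chaperone genes 4 fell, with SSC1 at -1.60 ± 0.26 (7 adjusted over the list alone, camera adjusted p = 3.63e-07, and adjusted p = 0.0585 with an estimated correlation). Of 79 large-subunit genes 1 rose and 5 fell (1 and 7 adjusted over the list alone), and of 57 small-subunit genes 4 fell (4 adjusted over the list alone), with camera adjusted p-values of 5.82e-06 and 0.00193 downward and adjusted p = 0.561 and 0.695 with an estimated correlation. Both lists stood above other genes in input and below them here. The haploid and pheromone (5 of 15 rose, 8 rose and 1 fell adjusted over the list alone), a-specific (6 of 7 fell) and α-specific lists (4 of 4 rose) held with an estimated correlation (adjusted p = 0.00184, 7e-05 and 7e-05).

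Smaller shifts downward that lost their call with an estimated correlation were those of 20 tricarboxylic acid cycle genes (4 fell, 6 adjusted over the list alone, adjusted p = 0.0619), 38 nuclear respiratory chain genes (5 fell, 6 adjusted over the list alone, adjusted p = 0.493) and 18 phosphate genes (2 fell, 3 adjusted over the list alone, adjusted p = 0.0619). The same held for 30 ergosterol and anaerobic genes (1 rose and 3 fell, 1 and 6 adjusted over the list alone, adjusted p = 0.0619), 18 purine genes (2 fell, 4 adjusted over the list alone, adjusted p = 0.467) and 41 oxidative stress genes (1 fell, 3 adjusted over the list alone, adjusted p = 0.487). The purine calls included IMD2 at -1.83 ± 0.33, and the ergosterol list's calls included DAN1, with 1 count against 26 in wild type (ratio 51.1, 95% counting interval 8.39 to 2090). The 6 mitochondrially encoded genes were higher as a list with 0 called by edgeR and 0 adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). The camera adjusted p-values of these 7 lists were at most 0.0261.

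The 177 calls fell to 95 without wild-type heavy polysome replicate 1, 65 without ΔRPL22A replicate 1 and 81 without ΔRPL22A replicate 2. Without the 4 libraries whose profiles lay closest to another pool, an alternative chosen after the data were seen, 487 genes passed, and with only the compared groups fitted 82. Without ΔRPL22A replicate 1 calls ended for TDH1 (adjusted p = 0.0538) and for the large-subunit (0.095), small-subunit (0.434), respiratory chain (0.141), oxidative stress (0.0727), ergosterol (0.141) and purine lists (0.091). Without wild-type replicate 1 they ended for the small-subunit (0.299), respiratory (0.131), oxidative stress (0.314), phosphate (0.111), ergosterol (0.226) and purine lists (0.314), and without wild-type replicate 2 for the mitochondrially encoded list (0.192). With ribosomal DNA rows left out 211 genes passed, 114 higher and 97 lower, moving the higher share from 42.4% to 54.0%, and DESeq2 called 197.

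Heavy polysomes of ΔRPL22B differed from wild type at 17 genes, 9 higher and 8 lower, 12 of them targeted genes or on the mating-type and marker lists. The other 5 were SHB17, AFB1, HMRA1, POS5 and NFG1, the last 4 named after their values were seen. MF(ALPHA)1 (9.49 ± 0.60), MF(ALPHA)2 (8.17 ± 0.56) and SAG1 (3.99 ± 0.42) rose, STE2 fell by 5.18 ± 0.48, and MFA2, LYS2 and RPL22B were at 0 counts against 380, 228 and 132, at least 142-fold, 84.9-fold and 49.2-fold lower. SHB17 rose by 3.81 ± 0.36 (adjusted p = 2.53e-08). The a-specific list (5 of 7 fell, 6 adjusted over the list alone) and the α-specific list (4 of 4 rose) held with an estimated correlation (adjusted p = 3.15e-06 for each). In the Gcn4 list (46), the ribosome biogenesis list (107), the translation factor list (43) and the mitochondrial ribosome list (70) edgeR called 0 genes, and 0 adjusted over the list alone. The first 3 were lower and the last higher by camera (adjusted p = 0.00486, 3.7e-05, 0.0051 and 0.0051), and with an estimated correlation the adjusted p was 0.728, 0.728, 0.18 and 0.728. The list at the RPL22 loci passed here as well (camera adjusted p = 0.0051, and adjusted p = 0.0611 with an estimated correlation) and holds the deleted RPL22B. LYS9 was at -0.82 ± 0.24 and MRPL9 at 1.45 ± 0.49.

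DESeq2 called 15 genes, and 261 had an unadjusted p under 0.05, near the share of 0.05 that no change would give. The 4 lists without called genes lost their call without ΔRPL22B heavy polysome replicate 1 (adjusted p = 0.293, 0.0747, 0.204 and 0.0747) and also without wild-type replicate 1 (Gcn4 0.0543, translation factors 0.0531, mitochondrial ribosome 0.184) or replicate 2 (biogenesis 0.0706). The 2 strains' heavy polysome comparisons shared 9 higher and 7 lower calls with 1 opposite (0.13 and 0.15 for independent lists, 0 simulated), with a covariance of 0.392 against 0.232 simulated and r = 0.543 against 0.588. The opposite gene was RPL22B, and 12 of the 17 genes called in ΔRPL22B were targeted genes or on the mating-type and marker lists. Without the targeted genes and the mating-type and marker lists the covariance was 0.273, above the simulated covariance for all genes. The r of 0.469 was below the simulated r for all genes. Wild-type heavy polysomes, the group in common, had a duplicate chi-square per degree of freedom of 9.81, while the simulations took the spread from all groups. The higher covariance therefore cannot be told from the spread of these 2 libraries.

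Whether mRNAs were redistributed toward heavy polysomes was tested as the heavy polysome to input ratio between strains. EdgeR called 0 of 5380 genes for ΔRPL22A against wild type (376 at an unadjusted p under 0.05), 0 for ΔRPL22B against wild type (122) and 0 for ΔRPL22A against ΔRPL22B (660), and DESeq2 called 0 in each. The last comparison gave 145 genes with only the compared groups fitted, 10 without the 4 libraries closest to another pool and 5 without the low-count filter, and the first and second gave 1 each without the 4 libraries. The 122 for ΔRPL22B against wild type is a smaller share of the tested genes than 0.05. So are the counts of this comparison for the light polysome and monosome ratios below. RPL22B itself had a ratio difference of 0.27 ± 0.42 between ΔRPL22A and wild type. As lists, ribosomal protein genes had lower ratios in ΔRPL22A than in wild type: large-subunit genes stood -0.81 and small-subunit genes -0.64 from other genes (camera adjusted p = 8.33e-17 and 4.42e-09), and against ΔRPL22B -1.09 and -0.98 (1.72e-21 and 2.44e-15). None of these held with an estimated correlation (adjusted p = 0.495, 0.648, 0.382 and 0.493), and 0 members passed, also adjusted over the list alone. RPL18B was at -1.44 ± 0.39 against wild type and -1.46 ± 0.39 against ΔRPL22B. Ribosome biogenesis genes had higher ratios, by 0.29 and 0.47 (0 of 107 called, also adjusted over the list alone, camera adjusted p = 0.000397 and 3.91e-07, and adjusted p = 0.648 and 0.493 with an estimated correlation).

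In the same 2 comparisons nuclear respiratory chain, glycolysis and oxidative stress genes had lower ratios, with camera adjusted p-values of 0.000159, 0.000146 and 0.000215 against wild type and 1.09e-05, 0.00271 and 1.09e-05 against ΔRPL22B. With an estimated correlation the adjusted p was 0.495 for each against wild type and 0.382, 0.548 and 0.382 against ΔRPL22B. The thioredoxin gene TRX3 was at -1.63 ± 0.68 and -1.91 ± 0.65. Against ΔRPL22B, mitochondrial ribosome genes also had lower and cell cycle genes higher ratios (camera adjusted p = 0.00608 and 0.00125, and adjusted p = 0.548 and 0.381 with an estimated correlation). In ΔRPL22B against wild type, large-subunit, small-subunit and mitochondrial ribosome genes stood 0.28, 0.34 and 0.27 above other genes and biogenesis genes -0.18 (camera adjusted p = 0.0257, 0.00548, 0.0186 and 0.0459, and adjusted p = 0.998 for each with an estimated correlation). In all these lists edgeR called 0 members, also adjusted over the list alone.

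In ΔRPL22A against wild type the biogenesis list lost its call without ΔRPL22A input replicate 1 (adjusted p = 0.207) and glycolysis without ΔRPL22A heavy polysome replicate 1 (0.182). Against ΔRPL22B the mitochondrial ribosome list did so without the former (0.182) and glycolysis without the latter (0.337), and 1 gene passed without the latter. In ΔRPL22B every list named lost its call without wild-type heavy polysome replicate 2 (0.82 for large-subunit, small-subunit and biogenesis genes) or, for mitochondrial ribosome genes, replicate 1 (0.278). Without ΔRPL22B heavy polysome replicate 1 the 4 lists also lost it (0.461, 0.131, 0.131 and 0.794 for the large-subunit, small-subunit, mitochondrial and biogenesis lists). Leaving out wild-type input replicate 2 did so for the large-subunit (0.0763), mitochondrial (0.264) and biogenesis lists (0.406), ΔRPL22B input replicate 2 for the large-subunit (0.176) and biogenesis lists (0.302), and wild-type input replicate 1 for the large-subunit list (0.0618).

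In the light polysome to input ratio, 3 genes passed for ΔRPL22A against wild type, all lower: the mitochondrially encoded ATP synthase genes ATP6 (-5.13 ± 0.80, adjusted p = 0.00314) and OLI1 (-3.59 ± 0.65, adjusted p = 0.0187), and PMP1, a plasma membrane ATPase regulator (-2.42 ± 0.48, adjusted p = 0.0424). OLI1 stood at 20.5 ± 6.84 CPM in wild-type input and 31.2 ± 13.7 in wild-type light polysomes, against 19.2 ± 3.04 and 2.46 ± 0.06 CPM in ΔRPL22A. ATP6 is counted low, with 12 counts in ΔRPL22A light polysomes. In input, ATP6 stood at 1.94 ± 1.11 CPM in wild type and 9.41 ± 1.53 in ΔRPL22A, and PMP1 at 5.73 ± 0.34 and 16.1 ± 4.49. In light polysomes, ATP6 stood at 6.25 ± 2.87 and 0.81 ± 0.33 CPM, and PMP1 at 24.3 ± 2.11 and 12.8 ± 1.19. Higher input therefore also lowered these 2 ratios. Of 6 mitochondrially encoded genes 2 fell (6 adjusted over the list alone, camera adjusted p = 1.11e-09, and adjusted p = 0.113 with an estimated correlation). How mitochondrially encoded RNA came to lie in the gradient pools was not tested. Its ratios, here and in the other pools, are therefore not read as shifts in translation. Large-subunit, small-subunit, mitochondrial ribosome and nuclear respiratory chain genes had lower ratios as lists (camera adjusted p = 1.75e-08, 2.19e-10, 0.0249 and 0.000204, and adjusted p = 0.557, 0.52, 0.581 and 0.427 with an estimated correlation), with 0 called by edgeR and 0, 1, 0 and 2 lower adjusted over the list alone. Ribosome biogenesis, translation factor, purine, one-carbon, Gcn4, proteasome, glycolysis and cell cycle lists had higher ratios, with 0 members called by edgeR, 0 adjusted over the list alone and camera adjusted p-values from 1.41e-06 to 0.0484. Their lowest adjusted p with an estimated correlation was 0.163, for translation factors. The ratio of RPL22B was 0.34 ± 0.41 and did not pass.

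Leaving out 1 library gave between 0 and 4 calls. ATP6 lost its call without wild-type light polysome replicate 1 (adjusted p = 0.299). OLI1 did so without that library (0.299), wild-type input replicate 2 (0.188), ΔRPL22A input replicate 1 (0.173), or ΔRPL22A light polysome replicate 1 (0.0835) or 2 (0.121). PMP1 did so without wild-type input replicate 1 (0.36) or 2 (0.323), wild-type light polysome replicate 1 (0.299) or 2 (0.105), ΔRPL22A input replicate 1 (0.48), or ΔRPL22A light polysome replicate 1 (0.0878) or 2 (0.128). The count was 0 without wild-type light polysome replicate 1 and 1 without wild-type input replicate 2, ΔRPL22A input replicate 1 or ΔRPL22A light polysome replicate 2. PMP1 also lost its call with a block for the replicate number (edgeR adjusted p = 0.0591). At an unadjusted p under 0.05 417 genes passed, and DESeq2 called 4. Without the low-count filter 14 genes passed, without the 4 libraries closest to another pool 18 and with only the compared groups fitted 6. For ΔRPL22B against wild type edgeR called 0 genes (114 at an unadjusted p under 0.05) and DESeq2 0.

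In that ΔRPL22B comparison the large-subunit and small-subunit lists stood at -0.25 and -0.28 from other genes (camera adjusted p = 0.0149 for each, and adjusted p = 0.993 with an estimated correlation). Both turned to 0.26 and 0.32 without ΔRPL22B light polysome replicate 1. Of all libraries that one lay closest to another pool, correlating at 0.933 with its replicate and 0.931 with ΔRPL22A input replicate 1. Ribosomal protein genes took 45.3% of its counts outside the ribosomal DNA, against 58.9% in its replicate. Both lists lost their call without wild-type light polysome replicate 1, and the small-subunit list also without ΔRPL22B input replicate 1. The mitochondrially encoded list, with 0 called by edgeR and 0 adjusted over the list alone, had a lower ratio (camera adjusted p = 0.0149, and adjusted p = 0.732 with an estimated correlation). Ratios of a-specific and α-specific genes are not given for any pool, since one strain of each comparison with wild type has counts near 0.

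The monosome to input ratio gave 0 calls by edgeR for ΔRPL22A (398 at an unadjusted p under 0.05) and 0 for ΔRPL22B (94), and 0 by DESeq2 in each. As lists, the 6 mitochondrially encoded genes and 30 iron genes had lower ratios in ΔRPL22A, and 107 biogenesis genes and 22 cell cycle genes higher ones (camera adjusted p = 0.00104, 0.00109, 0.000862 and 0.00824, and adjusted p = 0.47, 0.417, 0.701 and 0.47 with an estimated correlation). Adjusted over the list alone, 4 mitochondrially encoded genes were lower and 2 cell cycle genes higher, and 0 of the other lists. COB was at -2.67 ± 0.81 and the cyclin gene CLB1 at 1.59 ± 0.48. The biogenesis list lost its call without ΔRPL22A input replicate 1 (adjusted p = 0.155), and 2 genes passed without ΔRPL22A input replicate 2. With only the compared groups fitted 4 genes passed in ΔRPL22A and 1 in ΔRPL22B, and without the 4 libraries 1 in ΔRPL22A. RPL22B had a ratio of -0.04 ± 0.41 in ΔRPL22A.

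Within wild type, heavy polysomes and monosomes were compared to describe the gradient itself. The largest changes toward monosomes were those of the ribosomal protein genes RPL41B (-4.65 ± 0.69), RPL41A (-3.71 ± 0.64), RPS26A (-4.02 ± 0.45) and RPS29B (-3.70 ± 0.42), OST4 of the oligosaccharyltransferase (-3.94 ± 0.47), LDB18 (-3.91 ± 0.64), COA2 (-3.62 ± 0.53) and the mitochondrially encoded OLI1 (-5.43 ± 0.59). ADH1 (2.78 ± 0.48), ADH2 (3.04 ± 0.48), the nucleolar methyltransferase gene NOP1 (2.24 ± 0.27), the co-chaperone gene SBA1 (2.23 ± 0.32), IMP21 (3.46 ± 0.36) and SBP1 (2.46 ± 0.42) lay toward heavy polysomes. So did 2 rows in the ribosomal DNA, YLR154C-G (2.59 ± 0.92) and YLR154W-B (2.43 ± 0.81). GCN4, whose mRNA carries upstream open reading frames, lay toward monosomes (-1.71 ± 0.29, adjusted p = 0.000201), as did RPL22B (-1.31 ± 0.31). Altogether 1200 genes passed, 555 toward heavy polysomes and 645 toward monosomes. The median gene length was 1707 bp for 553 of the former and 784.5 bp for 632 of the latter.

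Of 43 translation factor genes 17 lay toward heavy polysomes and 1 toward monosomes (24 and 2 adjusted over the list alone, camera adjusted p = 5.87e-07, and adjusted p = 0.0376 with an estimated correlation), among them PAB1 (1.96 ± 0.29), TIF3 (1.84 ± 0.26) and SUP35 (1.80 ± 0.33). Of 107 biogenesis genes 28 lay toward heavy polysomes and 1 toward monosomes (32 and 2 adjusted over the list alone, adjusted p = 0.352 with an estimated correlation). The counts toward heavy polysomes were 13 of 22 for glycolysis (15, and 1 toward monosomes, adjusted over the list alone, 0.261), 11 of 35 for the proteasome (13 adjusted over the list alone, 0.058) and 11 of 21 for chaperones, with 1 toward monosomes (13 and 1 adjusted over the list alone, 0.18). Of the Gcn4 list 11 of 46 lay toward heavy polysomes and 3 toward monosomes (11 and 4 adjusted over the list alone, adjusted p = 0.589 with an estimated correlation). Toward monosomes lay 31 of 79 large-subunit genes, with 5 the other way (34 and 5 adjusted over the list alone, 0.589), 19 of 57 small-subunit genes (20 adjusted over the list alone, 0.589), 18 of 70 mitochondrial ribosome genes (21 adjusted over the list alone, 0.261) and all 6 mitochondrially encoded genes, COX1 not with a block for the replicate number within strain (6 adjusted over the list alone, 0.253). So did 7 of 19 genes of the unfolded protein response (9 adjusted over the list alone, 0.099) and 5 of 7 a-specific genes (5 adjusted over the list alone, 0.13). In these 2 sentences the last number in each bracket is the adjusted p with an estimated correlation. The camera adjusted p-values of these 12 lists were at most 0.0167.

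The count of 1200 fell to 606 without wild-type monosome replicate 1, 667 without monosome replicate 2 and 456 without heavy polysome replicate 2, and DESeq2 called 965. RPL22B lost its call without heavy polysome replicate 2 (adjusted p = 0.0812), as did the a-specific list (0.0848), and the Gcn4 list lost its call without heavy polysome replicate 1 (0.0535). YLR154C-G and YLR154W-B lost theirs without monosome replicate 1 (0.267 and 0.221), monosome replicate 2 (0.0744 and 0.0638) or heavy polysome replicate 2 (0.213 and 0.194), and YLR154C-G without heavy polysome replicate 1 (0.0565).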

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

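The tests of the mating-type pattern, the first 2 of the Gcn4 list and the first and last of the pools were chosen after the result was seen, and the others before. A difference between groups marked the 283 genes whose input level differed between ΔRPL22A and ΔRPL22B, since the effects of the 2 deletions against wild type differ by this test. A difference between groups also marked the 3 genes whose light polysome to input ratio differed between ΔRPL22A and wild type, ATP6, OLI1 and PMP1.

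The mating-type and marker genes differed between wild type and both deletion strains. All 24 libraries showed the complete set of their strain, as wild-type cells of another mating type and marker background would give. Cells of the other type mixed in were ruled out as the source, since the other type's genes reached at most 2.97% of their level in the strain that expresses them (ΔRPL22B monosome replicate 2), where at least 20% was required. MET17 had 0 counts in every wild-type library and at least 14 in every deletion library. LYS2 had at least 34 and at most 1, and HMRA1 at least 13 and 0. This all-or-none split in both deletions argues against loss of a paralog as the source of the whole pattern. Whether that loss has a smaller effect on these genes cannot be told, since 0 of 16 deletion libraries have the wild-type background.

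The Gcn4 list stood higher in ΔRPL22A input. The comparison with ΔRPL22B holds no wild-type library, and there the list stood 0.844 above other genes (camera adjusted p = 9.81e-18, and adjusted p = 0.0502 with an estimated correlation). This argues against the background of the wild type as the whole cause. It does not rule it out, since the call did not hold with an estimated correlation. Without ΔRPL22A input replicate 1 the list stood at 0.738, so its size did not rest on that library alone. That fit leaves 1 library in the group, so only the effect size is given. A trend with gene length and expression level cannot be excluded. Its removal took the 46 genes from 0.889 to 0.726 ± 0.314 (error widened for their correlation of 0.17). The deletion strains differ at HIS3, with 28.67 and 23.81 CPM in ΔRPL22A input and 7.75 and 7.77 in ΔRPL22B input. Wild-type input had 7.89 and 8.1 CPM. Whether this is a marker difference or part of the rise in amino acid genes was not tested. As a hypothesis, more GCN4 mRNA in heavy polysomes of ΔRPL22A could raise the list, but the heavy polysome to input ratio of GCN4 differed from ΔRPL22B by 0.228 ± 0.396, which cannot tell.

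Of the variation between pools, the contrast of input and heavy polysomes with the other pools took the larger share, and a smaller contrast set input and light polysomes apart from monosomes and heavy polysomes (50%, 47.2% and 42.2% against 30.6%, 33.1% and 38.5% in wild type, ΔRPL22A and ΔRPL22B). The wild-type light polysome level lay between the monosome and heavy polysome levels in 54.3% of the 1576 genes that differ between those, which restates the smaller contrast and leaves the order of the pools along a gradient open as its cause. A trend with gene length was ruled out as the whole cause, since the smaller contrast correlated between wild type and ΔRPL22B at 0.787 before and 0.807 after its removal. A preparation step shared by 2 pools cannot be told apart from the pools, although YLR154W-E took at least 46.97% of ribosomal DNA counts in monosomes and heavy polysomes and at most 20.41% in the others. No biological explanation was tested for this pattern.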

How the results depend on the processing

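Of 327 named gene calls, 326 held with relative log expression scaling, 322 without the low-count filter, 325 with scaling without ribosomal protein and mitochondrial genes, 324 of 325 without ribosomal DNA rows and 304 of 312 by DESeq2, but 295 without the 4 libraries closest to another pool and 292 of 319 with only the compared groups, and 0 reversed. With each library left out in turn 156 held every time and 171 were lost at least once. Of 98 list calls followed through the alternatives, 98 held with relative log expression scaling, 97 without ribosomal DNA rows, 83 without the 4 libraries (13 lost and 2 reversed) and 16 with an estimated correlation, and 65 held with every library left out in turn (33 lost, 2 of them reversed). Few libraries per group and 314212 to 1950344 counts outside the ribosomal DNA limit the smaller changes.

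With 1 library left out, counts of genes ranged from 58 to 375 for ΔRPL22A and wild-type input, 38 to 490 for ΔRPL22A and ΔRPL22B input, 65 to 135 for ΔRPL22A heavy polysomes and 456 to 967 for the wild-type gradient. They ranged from 0 to 1 for heavy polysome to input between the deletion strains, 0 to 4 for light polysome to input and 0 to 2 for monosome to input in ΔRPL22A. Without the low-count filter the first of these ratios gave 5 genes and the second 14. Without the 4 libraries closest to another pool, chosen after seeing the data, ΔRPL22A heavy polysomes gave 487. The heavy polysome ratios then gave 1 (ΔRPL22A), 1 (ΔRPL22B) and 10 (between them), the light polysome ratio 18 and the monosome ratio 1 in ΔRPL22A. With only the compared groups fitted, input gave 545 (ΔRPL22A), 39 (ΔRPL22B) and 713 (between them), ΔRPL22A heavy polysomes 82, and the heavy polysome ratio between deletion strains 145. The light polysome ratio gave 6 and the monosome ratio 4 in ΔRPL22A and 1 in ΔRPL22B. Fewer libraries enter these fits, and the spread then comes from the compared groups alone. The cause was not tested further.

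With a block for the replicate number the input counts were 243, 18 and 274, heavy polysomes 170 and 17, the light polysome ratio in ΔRPL22A 2, the wild-type gradient 1114 and all other ratios 0, and with a block within strain the last 2 were 3 and 1076. The block for the replicate number ended the calls of SCW4 in ΔRPL22A input (adjusted p = 0.0517), of ERG20 (0.053) and GCN4 (0.0562) in input between the deletion strains, of PMP1 in the light polysome ratio (0.0591) and of ALD3 in the wild-type gradient (0.0535). The block within strain ended those of ALD3 (0.083), COX1 (0.0594), JLP1 (0.0516) and FAR1 (0.0566) in the wild-type gradient. Residuals of libraries with the same number correlated at -0.253 to 0.209 within strains and -0.401 to 0.122 within pools. Between groups that share neither strain nor pool the range was -0.324 to 0.302. The residuals thus show no pairing by number. They cannot exclude it, since the spread between duplicates could hide it, and the labels do not say what the numbers mark.

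The ratio of RPL22B in ΔRPL22A light polysomes turned to -0.098 without ΔRPL22A light polysome replicate 1 and rose to 0.676 without replicate 2. Its monosome ratio, near 0, lay between -0.26 and 0.224 with 1 library left out. It turned to 0.009 without wild-type input replicate 2 and 0.053 without wild-type monosome replicate 2. It turned to 0.224 without ΔRPL22A input replicate 1 and 0.029 without ΔRPL22A monosome replicate 1. Without the 4 libraries it turned to 0.232. In the ΔRPL22B light polysome ratio the large-subunit list ran from -0.788 to 0.261 and the small-subunit list from -0.884 to 0.322 with 1 library left out, and they turned to 0.269 and 0.322 without the 4 libraries. The cause was not tested.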

Other observations

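No hypothesis was tested in this part, and the genes named in it were chosen after their values were seen. The genes of oxidative stress defence did not move as a list in input of ΔRPL22A, against wild type (1 of 41 rose, 0 adjusted over the list alone, camera adjusted p = 0.371) or ΔRPL22B (2 rose and 1 fell, 4 and 2 adjusted over the list alone, adjusted p = 0.457). Against ΔRPL22B the glutaredoxin gene GRX7 rose by 1.36 ± 0.39 and the mitochondrial peroxidase gene CCP1 by 1.07 ± 0.30, and the glutathione transferase gene GTT1 fell by 1.22 ± 0.33, each lost with at least 3 of the 4 libraries left out singly. Of 27 one-carbon genes 4 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.544). The risers were the serine hydroxymethyltransferase gene SHM2 (1.16 ± 0.29) and the glycine cleavage genes GCV1 (1.17 ± 0.33), GCV2 (1.48 ± 0.32) and GCV3 (2.28 ± 0.38), and SAM2 (-1.49 ± 0.27) and CHO2 (-0.95 ± 0.28) were lower. SHM2 lost its call without ΔRPL22A input replicate 1 (adjusted p = 0.323) or ΔRPL22B input replicate 1 (0.15) or 2 (0.172), GCV2 without the same libraries (0.107, 0.135 and 0.0712) and SAM2 without the first of them (0.0683). For GCV1 and CHO2 these fits were not tabulated.

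The ergosterol and anaerobic list did not pass in ΔRPL22A input against wild type (5 of 30 fell, 1 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.547). Among the 5, DAN1 had 0 counts against 32 in wild type, at least 14.1-fold lower, and against ΔRPL22B, with 66 counts, it was at least 20.3-fold lower. TIR3 fell by 1.83 ± 0.42, TIR4 by -1.23 ± 0.33 and the farnesyl pyrophosphate synthetase gene ERG20 by -1.05 ± 0.25. TIR3 lost its call without wild-type input replicate 2 (adjusted p = 0.156) or ΔRPL22A input replicate 1 (0.164), and ERG20 without wild-type input replicate 1 (0.0763) or 2 (0.147) or ΔRPL22A input replicate 1 (0.25). Of 14 genes with upstream open reading frames, 3 rose against ΔRPL22B (3 adjusted over the list alone, camera adjusted p = 0.301), namely GCN4, CPA1 (1.13 ± 0.25) and LEU4 (1.55 ± 0.29). CPA1 lost its call without ΔRPL22A input replicate 1 (0.12) or ΔRPL22B input replicate 1 (0.171), and LEU4 without the latter (0.0876).

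RPL22A was not alone among ribosomal protein genes in being nearly uncounted, since over 24 libraries RPL39 had 51 counts, RPL43A 54 and RPL22A 68. The first principal component of the libraries took 30.4% of the variance and the second 19.8%. Over the wild-type gradient gene length correlated with the heavy polysome to monosome change at a rank correlation of 0.437.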
